A study of Mus musculus with 6 samples.

How the data were processed

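RNA from granulocyte/macrophage progenitors (GMPs), bone marrow cells that give rise to granulocytes and monocytes, was measured on 6 Affymetrix Mouse Genome 430 2.0 arrays. The cells came from wild-type (WT) mice, mice lacking IRF8 (IRF8 KO) and mice lacking both IRF4 and IRF8 (IRF4/8 DKO), with 2 arrays per genotype. Per the labels, each array came from a mouse, with 1 male and 1 female mouse per genotype, aged 12 to 22 weeks. The limma p-values of probe sets measure the spread between these samples only. Per the labels' protocols, cells were sorted as lineage-negative, IL-7R-negative, Sca1-negative, Kit-positive, CD34-positive and high for the Fc gamma receptors II and III, and biotin-labelled cRNA was made from 10 ng of total RNA.

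The deposited values are intensity values on a linear scale, which the authors normalized and computed with the model of the difference between perfect-match and mismatch probes in dChip 1.3, per the series' design text. The normalization method, the baseline array, the treatment of low values and any filter are not given in the sources used here. The 45037 probe sets ranged from 0.69 to 16563.28, with no value at or below 0. Arrays carry no depth, so their number limits the precision.

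Values were transformed to log2(value + 10.5), where 10.5 is the 25th percentile of all values. A fold change is therefore on the log2(value + pseudocount) scale, which understates the change of low genes. A probe set was kept if it lay above the 40th percentile of its array on at least 2 of the 6 arrays, which kept 29783 and left out 15254. Gene symbols came from a table of GEO's platform annotation, updated through gene identifiers against RefSeq genes of assembly GRCm38.p6, which was used for names and gene order only. Of all probe sets, 34945 had 1 symbol, 932 had several and 9160 had none in the table used. Probe sets with several or no symbols were tested and counted but not named. A gene was represented by its kept probe set with the highest mean log2 value, which gave 13267 genes.

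The 3 genotypes were fitted together with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with a trend on mean level, no covariates). Adjusted p-values are Benjamini-Hochberg values over all kept probe sets, with a threshold of 0.05. The fit had 3 residual degrees of freedom and 5.84 prior degrees of freedom. The 3 comparisons were: IRF8 KO against WT, IRF4/8 DKO against WT, and IRF4/8 DKO against IRF8 KO. Errors are standard errors (SE) of the limma fit over 2 arrays per genotype. Both comparisons against WT share the same WT arrays. The covariance that shared controls bring was therefore estimated from 100 simulations of unchanged groups, with the same spread in every genotype. Shared calls were counted in them too.

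Shifts of 22 gene lists were tested with limma's camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. That preset takes members as nearly independent, so these p-values rest mainly on the spread between genes, not between mice. The estimated correlation was 0.731 for azurophil granule, 0.721 for neutrophil maturation and 0.463 for erythroid genes, and as low as -0.118 for T and NK cell genes. Alternatives were camera with an estimated correlation, fry, and the mean over all probe sets of a gene. Fry is given as its directional test unless its mixed test, for change of members in either direction, is named. For members, counts are given over all probe sets and adjusted over the list alone.

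The samples, the tests of the comparisons, the gene lists and the rule for named genes were fixed before the data were examined, while several tests of technical explanations were chosen or changed afterwards, as stated with them. That rule named Irf8 and Irf4, the 10 genes with the largest rise and the 10 with the largest fall per comparison among those past the threshold with non-overlapping arrays, up to 4 members per list with the lowest adjusted p, and any IRF family member past the threshold. It was narrowed afterwards to lists with a camera adjusted p under 0.1 or a member past the threshold. Genes with the smallest p in IRF4/8 DKO against IRF8 KO, and other genes said to be so, were chosen after their values were seen.

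The alternatives tried were 2 other pseudocounts (3.9 and 39.23), no filter, a filter at the 60th percentile, quantile normalization, median centring, no variance trend, a robust variance, a fit of only the genotypes compared, sex as a block, age as a covariate, the replicate number as a block, and leaving out each array in turn. A comparison of both knockout genotypes together against WT, a split that used each WT array in only 1 comparison, and the IRF family list without Irf8 and Irf4 were added after seeing the data.

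The scripts were tested on simulated data with 200 of 29783 probe sets changed. With variances drawn from the fitted prior, the IRF8 KO against WT comparison recovered 0%, 4% and 92% of probe sets changed 2-, 4- and 16-fold, with 0, 0 and 11 false calls. The IRF4/8 DKO against WT comparison recovered 0%, 3% and 93.5%, with 0, 1 and 4 false calls. That simulation replaced an earlier form, which took the moderated variances of the fit as true. In the earlier form, 44.5% of 4-fold changes were recovered in IRF8 KO against WT and 48% in IRF4/8 DKO against WT. False calls then made up 11.9% and 14.3% of all calls at 4-fold. A simulated shift of 1 list was called, with 0 other lists called. The simulated noise was independent between probe sets, so this says nothing about false list calls where the genes of a list vary together.

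The 2 arrays of a genotype held the same value at 272, 218 and 262 probe sets in WT, IRF8 KO and IRF4/8 DKO. Xist and Y-linked signals matched the labelled sex in 6 of 6 arrays.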

Results

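Gene expression was measured in granulocyte/macrophage progenitors (GMPs) sorted from bone marrow of WT, IRF8 KO and IRF4/8 DKO mice. IRF8 and IRF4 are related transcription factors of blood and immune cells, and the series asks how their combined loss acts in the development of blood cancers. Each genotype had 2 arrays, from 1 male and 1 female mouse. Median intensity per array was 45.3 and 41.7 in WT, 38.6 and 38.4 in IRF8 KO, and 37.5 and 34.1 in IRF4/8 DKO. Across probe sets, which are not independent replicates, the arrays of a genotype correlated at r = 0.9683 in WT, 0.9122 in IRF8 KO and 0.9519 in IRF4/8 DKO. More than 2-fold differences between the arrays of a genotype were found for 1863, 7160 and 4230 probe sets, in the same order. WT replicate 2 and IRF4/8 DKO replicate 1 correlated at r = 0.9604, above the value within either knockout genotype.

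Irf8 signal was not lower in the knockout arrays. The first Irf8 probe set read 2588 and 3052 in WT, 3811 and 2602 in IRF8 KO, and 2611 and 4778 in IRF4/8 DKO. The second read 507 and 704, 1333 and 1131, and 934 and 1900. Irf4 was low in every array. Its first probe set read 32.1 and 23.5 in WT, 13.8 and 7.66 in IRF8 KO, and 66.0 and 54.6 in IRF4/8 DKO. Its second read 33.1 and 16.8, 29.7 and 14.1, and 11.8 and 20.2, and lay on the opposite side of WT in IRF4/8 DKO. No probe set of either gene passed the limma test in any comparison. Where the probe sets lie relative to the deleted parts is not given in the sources used here, so these values do not check the genotype labels.

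Loss of IRF8 was examined first, as IRF8 KO against WT. Tmem178, which codes for a transmembrane protein, rose 50.4-fold (log2 fold change 5.66 ± 0.45 SE, 2 arrays per genotype, limma adjusted p = 0.00848). Tctex1d1 rose 18.8-fold and Abca9, an ABC transporter gene, 18.7-fold, with another Abca9 probe set of the same sign not past the test. Ly86, whose protein MD-1 pairs with the Toll-like receptor homologue RP105, fell from a mean intensity of 600.1 to 3.96 (log2 fold change -5.40 ± 0.40 SE, limma adjusted p = 0.00848). Csrp3, a muscle LIM protein gene, fell 23.4-fold, and Tek, which codes for the angiopoietin receptor TIE2, fell from a mean of 200.9 to 6.92. Means of Ly86 and Tek in IRF8 KO and of Abca9 in WT (6.28) lay below the pseudocount of 10.5, which sets the size of their changes. The mean of Csrp3 in IRF8 KO (13.4) lay near it. With a pseudocount of 39.23 the log2 fold change of Ly86 was -3.89 (limma adjusted p = 0.0099), and Abca9 and Tek no longer passed (limma adjusted p = 0.0639 and 0.0539). The limma test called 9 of 29783 probe sets, 3 higher and 6 lower. Gm6958 and 2 probe sets without a single symbol, including an alpha-globin probe set, were among the lower ones (chosen after their values were seen). At an unadjusted p under 0.05 there were 4007, against 1489 expected by chance. The count was 34 after quantile normalization (47.1% higher) and 37 after median centring (45.9% higher), against 33.3% higher here. It was 2 with sex as a block, 136 with age and 209 with the replicate number as a block. It was 0 without WT replicate 1, 0 without WT replicate 2, 1090 without IRF8 KO replicate 1, 193 without IRF8 KO replicate 2, and 2 without either IRF4/8 DKO array.

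**Figure D1:**
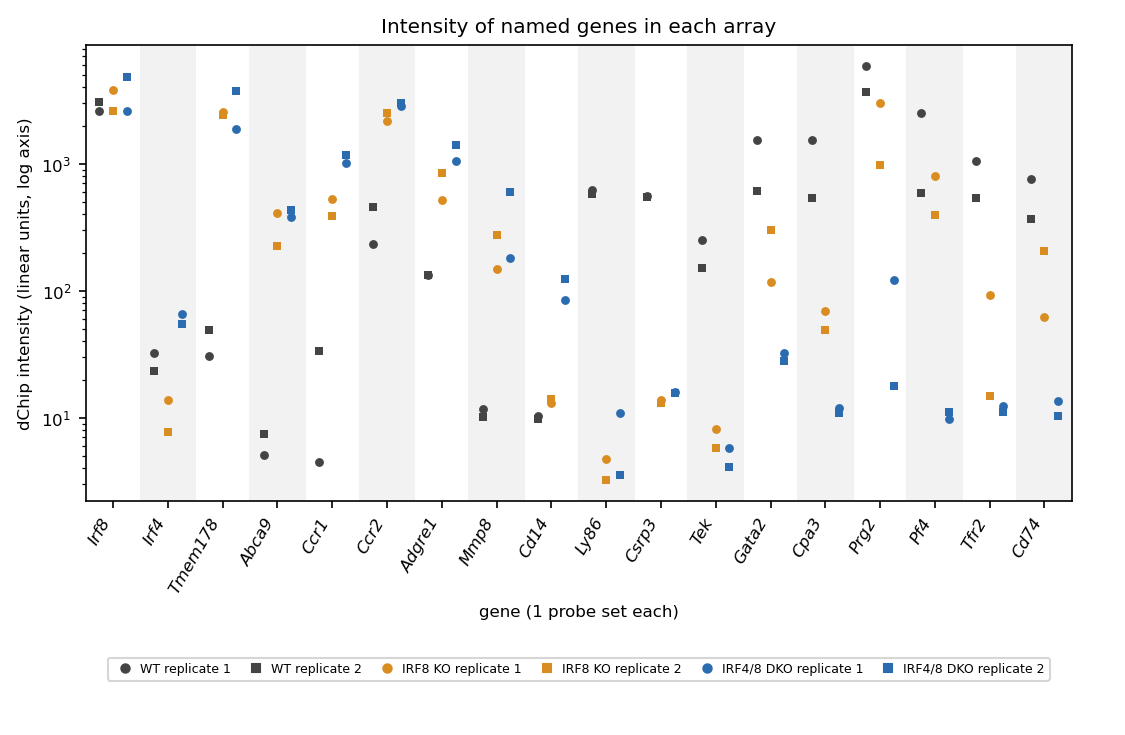
dChip intensity (linear units on a log axis) of 18 genes, by the representative probe set, with 1 point per array, coloured by genotype and shaped by replicate number. Tmem178 lies at 40.1 on average in WT and at 2500.1 and 2811 in IRF8 KO and IRF4/8 DKO, while Irf8 lies between 2588 and 4778 in all arrays.

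Lists of granulocyte and monocyte genes shifted upward in IRF8 KO. Genes of secondary granules and neutrophil maturation had a median log2 fold change of 0.94 over 22 measured members, 21 of them higher (camera adjusted p = 4.61e-05, and adjusted p = 0.756 with an estimated correlation). None of these members passed over all probe sets, and 3 were higher when adjusted over the list alone. The collagenase gene Mmp8 lay 9.95-fold and the chitinase-like gene Chil3 5.61-fold above WT (limma adjusted p = 0.0916 and 0.0996). Only Cxcr2, a chemokine receptor gene of neutrophils, lay below WT, 2.57-fold (limma adjusted p = 0.26). Set against the mean of WT, the list median per array was -0.55 and 0.55 in WT and 0.56 and 1.83 in IRF8 KO. The monocyte and macrophage list had a median of 0.61 over 21 members (adjusted p = 0.0104, and adjusted p = 0.447 with an estimated correlation). Over all probe sets 1 member fell, Ly86, and adjusted over the list alone 8 were higher and 3 lower. The chemokine receptor gene Ccr2 lay 6.90-fold and Mpeg1, a pore-forming macrophage protein gene, 3.39-fold above WT (limma adjusted p = 0.0509 and 0.0823). Azurophil granule genes had a median of 0.27 over 12 members (adjusted p = 0.0321, and adjusted p = 0.893 with an estimated correlation), with 0 past the test over all probe sets and 1 higher adjusted over the list alone, and Lyz1 lay 2.04-fold above WT. Cytokine receptor and JAK-STAT genes had a median of 0.56 over 30 members (adjusted p = 0.00284, and adjusted p = 0.398 with an estimated correlation). Of these, 0 passed either way. Ifngr1 lay 1.81-fold above WT, and Socs3, an inhibitor of this pathway, 3.46-fold below (limma adjusted p = 0.143 and 0.173). Between the male arrays the median log2 difference was 2.54 for neutrophil maturation and 0.692 for azurophil granule genes, and between the female arrays -0.231 and -0.117, a difference not tested with 1 array per sex and genotype. Without WT replicate 1 the adjusted p was 0.0772 for neutrophil maturation and 0.807 for azurophil granule genes. Without IRF8 KO replicate 2 it was 0.163, 0.514 and 0.163 for neutrophil maturation, azurophil granule and monocyte genes. The neutrophil maturation median was 0.486 and 1.81 without WT replicates 1 and 2, and 1.83 and 0.561 without IRF8 KO replicates 1 and 2. For azurophil granule genes it was 0.032, 0.46, 0.458 and 0.101 in the same order. The monocyte median was 0.396 without IRF8 KO replicate 2, and the cytokine receptor median 0.356 without WT replicate 2.

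Lists of stem cell genes and of other blood lineages shifted downward in IRF8 KO. Stem and progenitor genes had a median log2 fold change of -1.25 over 20 members, with 10 lower adjusted over the list alone and 0 over all probe sets (camera adjusted p = 1.07e-07, and adjusted p = 0.447 with an estimated correlation). The transcription factor gene Mecom lay 5.25-fold and Angpt1, which codes for a ligand of TIE2, 18.6-fold below WT (limma adjusted p = 0.0823 and 0.0988). The IRF8 KO mean of Mecom (10.6) lay near the pseudocount, on which the size of its change depends. Erythroid genes had a median of -1.90 over 11 members, all lower (adjusted p = 2.09e-06, and adjusted p = 0.474 with an estimated correlation). The erythroid transcription factor gene Gata1 lay below WT, at a mean under the pseudocount (7.34), and the carbonic anhydrase gene Car2 lay 10.2-fold below (limma adjusted p = 0.108 and 0.128). Eosinophil, basophil and mast cell genes had a median of -1.75 over 12 members, all lower (adjusted p = 1.82e-07, and adjusted p = 0.398 with an estimated correlation), with the mast cell protease gene Cpa3 13.3-fold below WT (limma adjusted p = 0.0631). Megakaryocyte genes had a median of -1.01 over 8 members (adjusted p = 0.0147, and adjusted p = 0.756 with an estimated correlation). Immediate early and stress genes had a median of -0.26 over 15 members (adjusted p = 0.0321, and adjusted p = 0.516 with an estimated correlation). Adjusted over the list alone, 4 erythroid, 7 eosinophil, basophil and mast cell, 0 megakaryocyte and 1 immediate early member were lower, and over all probe sets 0 in each. The megakaryocyte call was lost without WT replicate 1 (adjusted p = 0.294) and without IRF8 KO replicate 2 (0.514), as was the immediate early call (0.149 and 0.514). Medians between the male arrays were -2.63 for erythroid, -2.10 for megakaryocyte, -2.27 for eosinophil, basophil and mast cell and -0.693 for immediate early genes. Between the female arrays they were -0.247, -0.175, -0.745 and -0.138, differences not tested. The erythroid median was -0.925 without WT replicate 1 and -0.962 without IRF8 KO replicate 2, and the eosinophil, basophil and mast cell median -1.02 without IRF8 KO replicate 2. For megakaryocyte genes it was -0.242 without WT replicate 1 and -1.88 without WT replicate 2. The immediate early median was -0.142 and -0.469 without WT replicates 1 and 2, and -0.532 and -0.167 without IRF8 KO replicates 1 and 2. In all, 9 of 22 lists were called, 5 without WT replicate 1 and 4 without IRF8 KO replicate 2, and 0 with an estimated correlation or with fry. The 13 lists not called had camera adjusted p from 0.422 to 0.937. Their medians included -0.02 for cell cycle, 0.33 for cell cycle inhibitors, -0.15 for housekeeping, 0.18 for B and lymphoid, -0.02 for T and NK cell (5 members), -0.01 for genes near Irf8 and 0.26 for genes near Irf4. Median and mean differed in sign for genes near Irf8 (mean 0.18), dendritic cell genes (0.08 and -0.02), interferon-stimulated genes (0.009 and -0.05), reported IRF8 targets (0.02 and -0.11) and myeloid transcription factors (0.23 and -0.01). For apoptosis genes (0.08 and 0.02) camera gave a downward direction. Fry's mixed test gave adjusted p = 0.00453 for monocyte, for myeloid transcription factor and for B and lymphoid genes. It gave 0.0171 for stem and progenitor genes, 0.0322 for eosinophil, basophil and mast cell genes, and 0.0762 to 0.476 for the other lists.

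**Figure D2:**
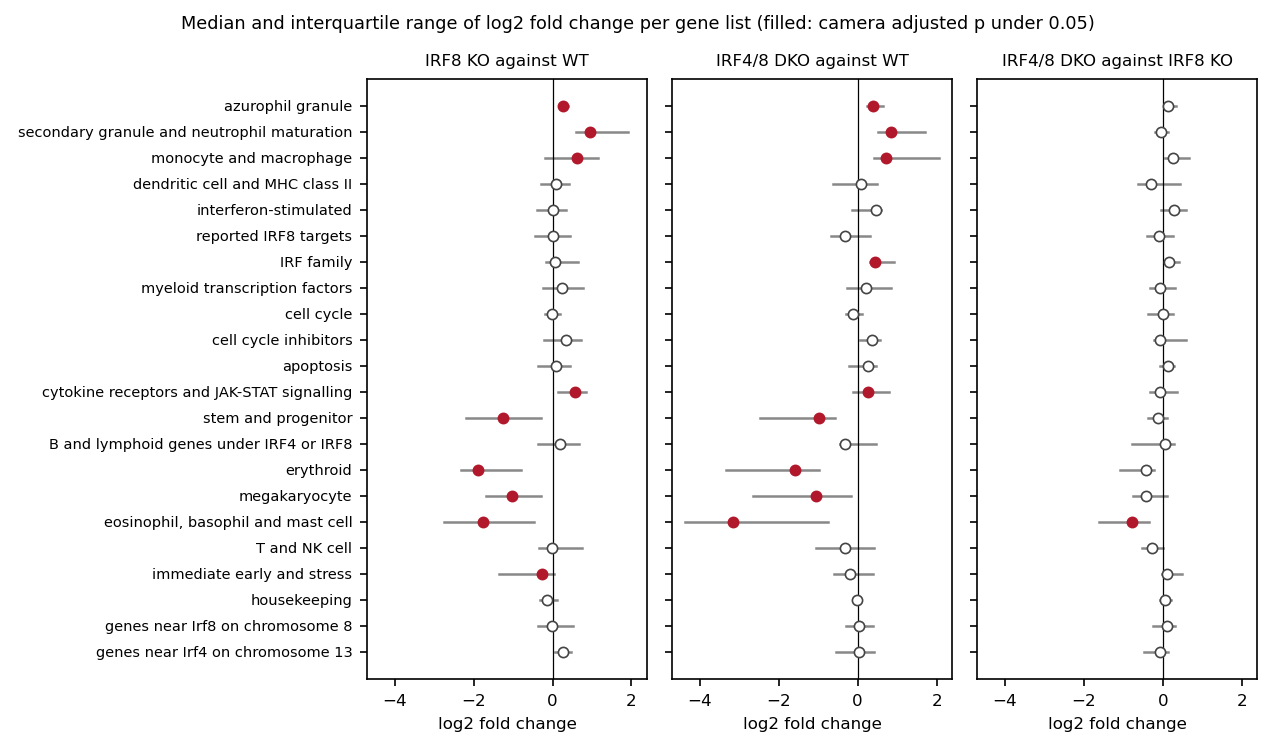
Median (points) and interquartile range (lines) of log2 fold change over the members of 22 gene lists in the 3 comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation. The eosinophil, basophil and mast cell list has its median at -1.75, -3.15 and -0.78 from left to right.

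Combined loss of IRF8 and IRF4 was examined as IRF4/8 DKO against WT. The chemokine receptor gene Ccr1 rose 43.1-fold (log2 fold change 5.43 ± 0.56 SE, 2 arrays per genotype, limma adjusted p = 0.0214). Tmem178 rose 53.4-fold, the sodium channel subunit gene Scnn1a 30.6-fold, Abca9 24.98-fold, the inhibitory receptor gene Siglece 16.4-fold, Mmp8 16.0-fold, Shisa2 13.4-fold, Tctex1d1 13.3-fold, Ptgfrn 11.05-fold and the homeodomain protein gene Hopx 10.2-fold. Prg2, which codes for eosinophil major basic protein, fell 76.2-fold, from a mean intensity of 4776 to 69.6 (log2 fold change -6.25 ± 0.75 SE, limma adjusted p = 0.0285). The platelet factor gene Pf4 fell to a mean of 10.5, Cavin2 to 2.05, the thrombin receptor gene F2r to 3.72 and Ly86 to 7.26, from means of 1553, 941.8, 793.2 and 600.1. Cpa3 fell 41.9-fold, the transferrin receptor gene Tfr2 34.3-fold, Grb10 33.98-fold, Rgs1 27.2-fold and Gata2, a transcription factor gene of stem and mast cells, 24.2-fold. Where a mean lay near or below the pseudocount of 10.5, the size of the change depends on it. In IRF4/8 DKO this held for Pf4, Cavin2, F2r, Ly86, Rgs1 (10.955), Cpa3 (11.4) and Tfr2 (11.7). In WT it held for Abca9, Ptgfrn (10.66) and Mmp8 (10.92). Of these genes with a mean at or below 10.5, Cavin2 and F2r no longer passed with a pseudocount of 39.23 (log2 fold change -4.23 and -3.95, limma adjusted p = 0.0962 and 0.0591). Of all 89 probe sets called, 63 still passed with that pseudocount. The other kept probe sets of Abca9, Ptgfrn, Hopx, F2r, Grb10 and Gata2 had the same sign and did not pass. The limma test called 89 probe sets, 27 higher and 62 lower, or 24 and 43 named genes, with 2696 at an unadjusted p under 0.05. The count was 0 without either WT array and without either IRF4/8 DKO array, 469 without IRF8 KO replicate 1 and 484 without IRF8 KO replicate 2. It was also 0 with sex as a block, 13 without the filter on low values and 27 without a variance trend. With age it was 229, with the replicate number as a block 216, and with only these genotypes fitted 476.

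The gene lists moved in IRF4/8 DKO as follows. Monocyte and macrophage genes had a median log2 fold change of 0.71 over 21 members (camera adjusted p = 1.32e-06, and adjusted p = 0.21 with an estimated correlation). Over all probe sets 4 members rose and 1 fell, against 9 and 2 adjusted over the list alone. Ccr2 rose 8.73-fold, Adgre1, the gene of the macrophage antigen F4/80, 8.62-fold and Mpeg1 4.19-fold, while Ly86 fell, and 1 of 3 other Ccr2 probe sets passed. Neutrophil maturation genes had a median of 0.84 over 22 members (adjusted p = 1.28e-06, and adjusted p = 0.433 with an estimated correlation), with Mmp8 past the test over all probe sets and 3 members higher adjusted over the list alone. Azurophil granule genes had a median of 0.39 over 12 members, 0 past the test over all probe sets and 3 higher adjusted over the list alone (adjusted p = 9.51e-05, and adjusted p = 0.433 with an estimated correlation). IRF family genes had a median of 0.43 over 8 members, 0 past the test either way (adjusted p = 0.0202, and adjusted p = 0.372 with an estimated correlation), and Irf1 lay 1.94-fold above WT (limma adjusted p = 0.428). The members included the targeted genes Irf8 and Irf4, and without them, a choice made after the data were seen, the other 6 had a median of 0.435 and were not called (camera adjusted p = 0.0913, and adjusted p = 0.426 with an estimated correlation). With all 8 members the call was lost without WT replicate 2, at a larger median of 0.563, and without IRF4/8 DKO replicate 2, at a median of 0.031. Cytokine receptor and JAK-STAT genes had a median of 0.26 over 30 members, 0 past the test either way (adjusted p = 0.0094, and adjusted p = 0.263 with an estimated correlation). Without WT replicate 2 their adjusted p was 0.0623. The neutrophil maturation median was 0.442 and 1.41 without WT replicates 1 and 2, and 1.85 and 0.244 without IRF4/8 DKO replicates 1 and 2. Azurophil granule genes gave 0.178 and 0.695 without WT replicates 1 and 2, and 0.216 without IRF4/8 DKO replicate 2. The IRF family median was 0.77 and 0.031 without IRF4/8 DKO replicates 1 and 2, with 0.083 between the male and 0.912 between the female arrays. Without WT replicate 1 the monocyte median was 1.12 and the cytokine receptor median 0.429.

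Among the lists that shifted downward in IRF4/8 DKO, eosinophil, basophil and mast cell genes had a median log2 fold change of -3.15 over 12 members, all lower (camera adjusted p = 7.83e-17, and adjusted p = 0.21 with an estimated correlation). Prg2, Cpa3 and Ms4a2, the gene of an IgE receptor subunit, fell over all probe sets, and 8 members were lower adjusted over the list alone. The other Ms4a2 probe set had the same sign and did not pass. Erythroid genes had a median of -1.59 over 11 members, all lower, 0 past the test over all probe sets and 7 adjusted over the list alone (adjusted p = 1.86e-10, and adjusted p = 0.263 with an estimated correlation). Car2 lay 26.9-fold below WT (limma adjusted p = 0.0518). Stem and progenitor genes had a median of -0.99 over 20 members (adjusted p = 1.51e-10, and adjusted p = 0.263 with an estimated correlation), with Gata2 lower over all probe sets and 8 lower adjusted over the list alone by their representative probe sets. Angpt1 passed by its other probe set (log2 fold change -3.87, limma adjusted p = 0.0285) and not by the representative one (-4.41, limma adjusted p = 0.0812). Megakaryocyte genes had a median of -1.06 over 8 members (adjusted p = 6.09e-05, and adjusted p = 0.372 with an estimated correlation), with Pf4 lower over all probe sets and 3 adjusted over the list alone. The erythroid median was -2.44 without WT replicate 2, with -2.55 between the male and -0.926 between the female arrays, and the megakaryocyte median -0.678 without WT replicate 1. The dendritic cell and MHC class II list was not called (adjusted p = 0.245), with a median of 0.08 and a mean of -0.37. Its members Cd74, the MHC class II invariant chain gene, and H2-Aa fell, with log2 fold changes of -4.58 and -3.17 (limma adjusted p = 0.0293 and 0.0285), and 1 of 2 other H2-Aa probe sets passed. The IRF4/8 DKO means of Cd74 (11.985) and H2-Aa (11.77) lay near the pseudocount. Adjusted over the list alone, 1 member was higher and 3 lower. Reported IRF8 targets had a median of -0.32 (adjusted p = 0.149), interferon-stimulated genes of 0.47 (adjusted p = 0.106), apoptosis genes of 0.26 (adjusted p = 0.72) and myeloid transcription factors of 0.22 with a mean of -0.01 (adjusted p = 0.371). In all, 9 of 22 lists were called, and 0 with an estimated correlation or with fry's directional test. Fry's mixed test gave adjusted p = 0.00632 for monocyte, dendritic cell, myeloid transcription factor and B and lymphoid genes. It gave 0.0104 for stem and progenitor and for eosinophil, basophil and mast cell genes, 0.0468 for T and NK cell genes, and 0.0604 to 0.772 for the other lists.

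**Figure D3:**
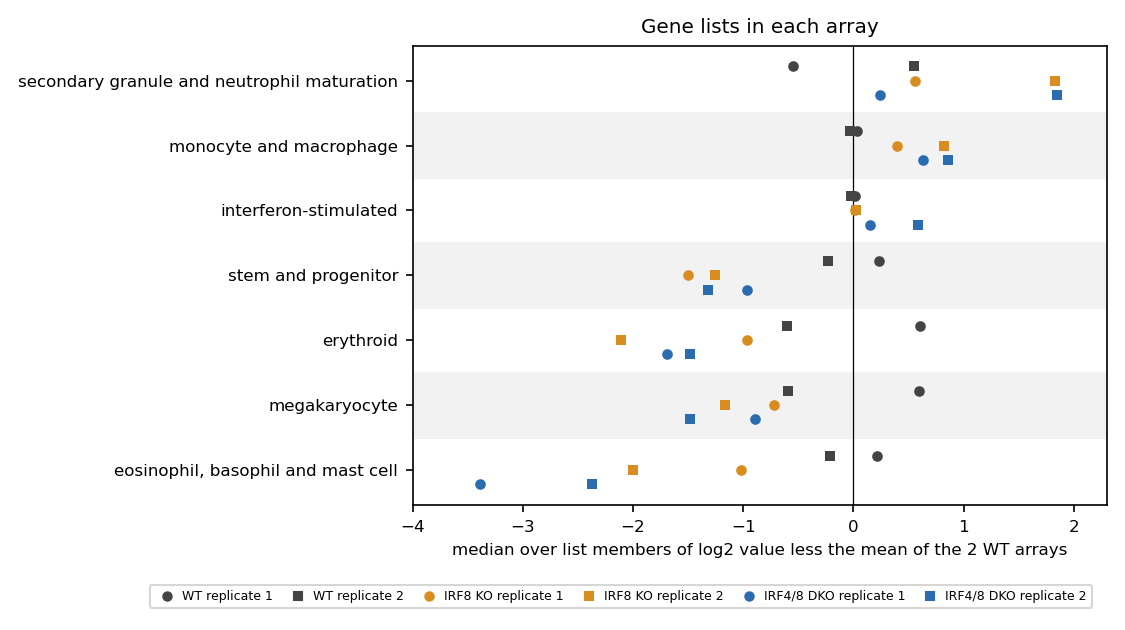
Median over list members of the log2 value less the mean of the WT arrays (horizontal axis), for 7 lists, with 1 point per array, coloured by genotype and shaped by replicate number. The eosinophil, basophil and mast cell list lies at -1.02 and -2.003 in IRF8 KO and at -3.39 and -2.38 in IRF4/8 DKO, and the neutrophil maturation list is higher in replicate 2 of each genotype.

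The addition of IRF4 loss was tested directly as IRF4/8 DKO against IRF8 KO. Eosinophil, basophil and mast cell genes shifted downward, with a median log2 fold change of -0.78 over 12 members, 11 of them lower (camera adjusted p = 0.000582, and adjusted p = 0.717 with an estimated correlation). Over all probe sets 0 members passed, and 1 was lower adjusted over the list alone. Prg2 lay 28.3-fold below IRF8 KO (mean intensity 69.6 against 2001.5, limma adjusted p = 0.364). Monocyte and macrophage genes had a median of 0.27 (adjusted p = 0.0592), with the lipopolysaccharide co-receptor gene Cd14 4.71-fold above IRF8 KO (mean intensity 103.9 against 13.5, limma adjusted p = 0.427). Interferon-stimulated genes had a median of 0.29 (adjusted p = 0.0516), with Rsad2 7.63-fold above (limma adjusted p = 0.508). Neither list was called, but without IRF4/8 DKO replicate 1 both were (adjusted p = 0.0381 and 0.0097). Among the genes with the smallest p, chosen after their values were seen, Pf4 (mean intensity 10.5 against 595.96) and H2-Aa (6.63-fold, mean intensity 11.77 against 138.2) lay below IRF8 KO, and Btla, an inhibitory receptor gene, 7.07-fold above (limma adjusted p = 0.364 for all 3). The limma test called 0 probe sets, with 2538 at an unadjusted p under 0.05 and a smallest adjusted p of 0.364. It called 200 without IRF8 KO replicate 1 and 14 without IRF8 KO replicate 2. The eosinophil, basophil and mast cell call was lost without IRF8 KO replicate 1 (median -0.428, adjusted p = 0.215), with a median of -1.38 without IRF8 KO replicate 2, and the number of lists called was 1, against 4 without IRF8 KO replicate 2, 5 without IRF4/8 DKO replicate 1 and 2 without IRF4/8 DKO replicate 2. Median and mean differed in sign for cell cycle genes (0.01 and -0.05), cell cycle inhibitors (-0.06 and 0.07), B and lymphoid genes (0.05 and -0.23), myeloid transcription factors (-0.06 and 0.006) and genes near Irf8 (0.11 and -0.02). For neutrophil maturation genes (-0.03 and -0.05) camera gave an upward direction. Fry's mixed test gave adjusted p = 0.0294 for dendritic cell and for B and lymphoid genes, and 0.0688 to 0.755 for the other lists.

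Changes against WT were then compared between the knockout genotypes. Tmem178, Abca9 and Tctex1d1 rose in both, and Ly86, Csrp3, Tek, Gm6958 and an alpha-globin probe set (Hba-a2 or Hba-a1) fell in both. These were 8 shared calls, 3 higher and 5 lower, with 0 in opposite directions. Independent lists of these sizes would share 0.00272 higher and 0.0125 lower calls. Simulated unchanged groups that shared their WT arrays had 0.03 shared calls. With no true change few probe sets can pass the adjusted threshold. The simulated count therefore cannot tell how much overlap shared controls bring to lists that hold changes. Over all probe sets 67.9% had the same sign, against 66.7% in the simulation. The fold changes correlated at r = 0.625, against 0.5 in the simulation, and their covariance was 0.32 against 0.114, a difference of 0.206. The simulation gave every genotype the same spread. In the data the WT arrays differed least, more than 2-fold at 1863 probe sets, against 7160 in IRF8 KO and 4230 in IRF4/8 DKO. Shared controls may therefore bring less agreement in sign, r and covariance than simulated. Part of the shared calls and of r may still come from the shared controls. A split added after the data were seen used each WT array in 1 comparison only. With WT replicate 1 set against IRF8 KO and replicate 2 against IRF4/8 DKO, r was 0.533, the covariance 0.286 and the same-sign share 65.4%. The other way round they were 0.313, 0.199 and 54.9%, so the covariances lay on either side of the difference of 0.206. The count of shared calls was 0 without either WT array or either IRF4/8 DKO array, 244 without IRF8 KO replicate 1 and 77 without IRF8 KO replicate 2.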

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

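The tests of age, sex and replicate number were chosen only after the result was seen. In IRF8 KO against WT, neutrophil maturation genes had a median log2 difference of 2.54 between the male arrays and -0.231 between the female arrays. For azurophil granule genes these medians were 0.692 and -0.117. Both lists stood out because male and female arrays went opposite ways, and the difference was not tested, with 1 array per sex and genotype.

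For the neutrophil maturation list, age, sex and replicate number were weighed, and each stays open. For age, the list was higher in the older mouse in WT (19 against 12 weeks, median 1.09 log2 units) and in IRF8 KO (22 against 12 weeks, 1.25), while the IRF4/8 DKO arrays, both from mice of 16 weeks, differed by 1.44, with 21 of 22 members higher in replicate 2. An earlier rule for this test had counted against age as the whole source from the IRF4/8 DKO value alone, and was changed after its result was seen. For sex, the list was higher in the female array in WT and IRF4/8 DKO and in the male array in IRF8 KO, and the male shift less the female shift was 2.77 in IRF8 KO and -0.2 in IRF4/8 DKO, so no value goes with an effect of sex shared by the knockout genotypes, while one in IRF8 KO alone was not tested. The list was higher in replicate 2 in 3 of 3 genotypes. Male mice were replicate 1 in WT and IRF4/8 DKO but replicate 2 in IRF8 KO. The male pair thus set IRF8 KO replicate 2 against WT replicate 1, and the female pair IRF8 KO replicate 1 against WT replicate 2. The gap between these pairs therefore restates that the list was higher in replicate 2 of both genotypes. A shared difference between replicates 1 and 2 may contribute, but the labels tie the number to no day or batch. Variation between single mice was not tested.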

How the results depend on the processing

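The comparison of both knockout genotypes together, the split of the WT arrays and the IRF family list without Irf8 and Irf4 were chosen only after the data were seen and are given elsewhere. The design written beforehand named sex, age, the estimated correlation and fry as alternatives, and did not name the other settings. Counts of calls moved widely, and the cause was not tested. IRF8 KO against WT (9 calls) gave 21 and 5 with the lower and higher pseudocount, 5 without a filter, 17 with the stricter filter, 34 with quantile normalization, 37 with median centring, 5 without a variance trend, 17 with a robust variance, 2 with only these genotypes, 2 with a sex block and 136 with age. Shared calls (8) gave 15, 5, 5, 14, 24, 26, 5, 15, 2, 0 and 84 in the same order. IRF4/8 DKO against WT (89) gave 13 without a filter, 27 without a variance trend, 476 with only these genotypes, 0 with a sex block and 229 with age, and with all arrays in the fit stayed within 1.5 times otherwise, except with the replicate block. IRF4/8 DKO against IRF8 KO (0) gave 2 with age. Lists called were 0 in each comparison with an estimated correlation and with fry's directional test. In IRF4/8 DKO against IRF8 KO (1 list) they were 2 with the higher pseudocount, 3 without a filter, 2 with median centring, 3 with only these genotypes, 5 with age and 3 with gene means. Leaving out 1 array gave 0 to 1090 calls in IRF8 KO against WT, 0 to 484 in IRF4/8 DKO against WT, 0 to 200 in IRF4/8 DKO against IRF8 KO and 0 to 244 shared. Lists called ranged from 4 to 9, 7 to 10 and 0 to 5 in these comparisons. The lone array left in a genotype was assumed to vary like the others. Only Irf8, never past the threshold, changed sign among named genes. Its log2 fold change ranged from -0.11 (without IRF8 KO replicate 1) to 0.44 in IRF8 KO against WT and from -0.11 (without IRF4/8 DKO replicate 2) to 0.76 in IRF4/8 DKO against WT. In IRF4/8 DKO against IRF8 KO it was -0.11 without IRF8 KO replicate 2, and ranged from -0.27 (without IRF4/8 DKO replicate 2) to 0.60. The labels tie replicate numbers to no shared animal or batch, and deviations of same-numbered arrays correlated at 0.041, 0.19 and 0.21 across probe sets, so the numbers were not taken to pair the samples, and a shared difference stays open. With the replicate block there were 209, 216 and 1 calls in the 3 comparisons, 122 shared calls, and 2 lists in IRF4/8 DKO against IRF8 KO. Of named genes, 1304 values outside leave-one-out kept their side of the threshold, 79 lost it, 75 gained it and 0 changed sign. Signals near the background limit low genes, whose fold changes rest on the pseudocount.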

Other observations

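The comparison of both knockout genotypes together with WT, the tests of red cells, platelets and sequence near Irf8 alone, and the final form of several tests named as such were chosen only after results were seen. Taken as 1 group against WT, the 4 knockout arrays gave 179 called probe sets in limma, 56 higher and 123 lower. Of these, 83 were also called in IRF4/8 DKO against WT. Cd33 rose by 2.97 log2 units (limma adjusted p = 0.0251), the lectin gene Clec4a2 by 2.37 (0.036) and Lrp1 by 2.98 (0.0325), while Ly86 fell by 5.27 (0.00236). The surrogate light chain gene Vpreb1 of the B lineage rose by 2.21 (0.0441), while Ikzf3, a lymphoid transcription factor gene, fell by 2.25 (0.036). Mecom, Gata2 and Angpt1 fell (log2 fold changes -2.42, -3.45 and -4.31), so 3 of 20 stem and progenitor members passed. These genes were chosen after their values were seen. The count was 0 without WT replicate 1, 0 without WT replicate 2, 1020 without IRF8 KO replicate 1, 678 without IRF8 KO replicate 2, 12 without IRF4/8 DKO replicate 1 and 4 without IRF4/8 DKO replicate 2.

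Megakaryocyte, erythroid and mast or eosinophil genes were lower in the knockout genotypes, and other cells in the WT sorts may have supplied them. Which cells the sort gates removed or kept was not tested. Stem and progenitor genes, also lower in both knockout genotypes, were not part of the tests that follow. Platelets stay open: Ppbp, Gp1bb and Tubb1 reached at most the 55.7th percentile of a WT array, but none of their 4 probe sets passed the filter on low values, and Ppbp read 64.6 and 11.4 in WT and 5.13 to 5.78 in the knockout arrays, so its lower level there rests mainly on WT replicate 1. Red cells stay open. Of 8 adult globin probe sets, 3 were lower by over 1 log2 unit in both knockout genotypes, and 0 of these lay above the 90th percentile in WT. Among these 3, an Hba-a2 or Hba-a1 probe set passed the limma test in both comparisons against WT (log2 fold change -3.31 and -3.12). Hbb-b2 passed in IRF4/8 DKO (-3.84, limma adjusted p = 0.0285). The probe set shared by the beta-globin genes lay at -0.05 in IRF8 KO and -0.81 in IRF4/8 DKO. The Hba-a2 probe set that reached the 97.9th percentile was not lower in IRF4/8 DKO (log2 difference 0.22, and -0.68 in IRF8 KO). For a single extra population supplying all these genes, the ratio between the WT arrays varied over 15 members by a median absolute deviation of 0.821, above the bound of 0.774 from matched lists that had been set beforehand to exclude it, but a bootstrap interval added after the value was seen was 0.271 to 1.28 and all 15 members were higher in WT replicate 1, so it stays open. Earlier forms had counted against platelets and against red cells, a joint test of both was undecided, and each was changed after its result was seen.

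More probe sets were called against WT in IRF4/8 DKO (89) than in IRF8 KO (9) at the adjusted threshold. At an unadjusted limma p under 0.05 the order was reversed, with 2696 in IRF4/8 DKO and 4007 in IRF8 KO. With a sex block the calls were 0 and 2, and with the replicate block 216 and 209. The other settings, leave-one-out aside, kept the order. Without either IRF4/8 DKO array the order was reversed, and without either WT array the counts were equal. Spread between the IRF8 KO arrays stays open: leaving out either gave 193 or 1090 calls in IRF8 KO against WT. However, this takes that spread out of every comparison, and IRF4/8 DKO against WT gave 484 or 469 in the same fits. Of the fits without an IRF8 KO array, the order of the counts thus turned only without replicate 1. An earlier rule, written before the result, set these counts against the 89 of all arrays and had counted for this explanation, and was changed after its result was seen. Larger changes in IRF4/8 DKO stay open: over the 100 genes farthest from WT in 1 IRF4/8 DKO array, the other lay 0.38 or 1.01 log2 units beyond IRF8 KO, and with genes chosen on 1 IRF8 KO array, IRF4/8 DKO lay 0.201 or 0.705 beyond the other IRF8 KO array. This test replaced a form that asked for calls in the direct comparison, after that comparison had given 0.

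A candidate explanation of some changes is donor-strain sequence beside the targeted genes. Of 54 genes called in IRF4/8 DKO against WT by their representative probe set, 2 (3.7%), Ly86 and Gcnt2, lay within 100 protein-coding genes of Irf4 and 0 near Irf8. Of all 13267 represented genes, 89 lay that near Irf4 and 147 that near Irf8. Ly86 also fell in IRF8 KO, where Irf4 is not targeted. With both knockout genotypes together Crispld2 near Irf8 was called too (log2 fold change 3.04, limma adjusted p = 0.0381), with 3.78 in IRF8 KO alone (limma adjusted p = 0.0693). Near Irf8 the odds ratio of an unadjusted p under 0.05 was 1.09 (95% interval 0.632 to 1.78) in IRF8 KO and 0.66 (0.278 to 1.34) in IRF4/8 DKO by Fisher's exact test (adjusted p = 1 for both), and near Irf4 0.927 (0.427 to 1.8) and 1.14 (0.474 to 2.36), so Crispld2 near Irf8 and the last bound, above the 2 set beforehand, near Irf4 keep it open. The joint test had been left out after its values were seen and was then restored as first written, and an earlier form of the test near Irf8 alone had counted against it before Crispld2 was taken in.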
